A study of Capra hircus with 12 samples.

How the data were processed

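The samples were 12 RNA-seq libraries from mammary gland biopsies of lactating dairy goats, 4 for each of 3 glucose doses, and the dose of each was taken from its treatment label. RNA was made into libraries with a TruSeq kit, per the labels' protocols. The authors deposited one table per library with raw read counts per gene, as whole numbers; one table of the middle dose names that column differently. The submitters' processing notes list Bowtie 0.12.2 and mm8, a mouse genome build, whereas the tables list goat genes with goat gene IDs and chromosomes. How reads were assigned to genes, whether strand was used and which goat build was used are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart, and members of gene families with near-identical sequence, such as the MHC genes, are uncertain.

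The tables came in 2 layouts, one of 16030 genes (4 libraries: high-dose replicates 1 and 4, low-dose replicate 3 and middle-dose replicate 1) and one of 15991 genes (the other 8). No label mentions this split, which was treated as a possible processing batch. The 15810 genes listed in both were used. The 220 genes listed only in the first and the 181 listed only in the second held counts of at most 23 in any library and at most 294 reads, or 0.0023% of a library. Gene IDs matched the NCBI annotation of ARS1.2 for 15384 genes (97.3%), which was used only for names; it gave 629 names and stood in for 22 names that a spreadsheet had turned into dates. Chromosome names matched for 98.0% of genes over 30 sequences. Coordinates are those of the tables, whose build is not named.

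Genes with low counts were removed by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13624 genes and removed 2186. Library composition was scaled by TMM, with factors from 0.514 to 1.50, and CPM values are counts relative to the scaled library size. The CPM of a gene that takes much of a library can therefore exceed its share of the reads. Each gene was tested with the quasi-likelihood F test of edgeR 4.0.16 on the counts of all 12 libraries, with dose as the only factor, and p-values were adjusted by Benjamini and Hochberg to a threshold of 0.05. The common biological coefficient of variation was 0.363. There were 3 comparisons of doses, a test of the middle dose against the mean of the other doses, and a test of any difference. Log2 fold changes are shown with standard errors, each taken as the size of the change divided by the square root of its F statistic. The prior count for log2 CPM was 2 and figures of single genes use log2(CPM + 1). Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, on voom values of the same genes, beside camera with an estimated correlation and fry. Of 40 lists, 37 had the 5 measured members required. Some genes are in more than 1 list. Single values per library were compared by exact permutation tests. R was 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

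Groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For each comparison of doses the rule takes the 10 largest increases and decreases among genes past the threshold that do not overlap between the groups. Where these are fewer than 10, it also takes the 10 genes with the smallest p, a symbol and a mean log2 CPM of at least 1. In each list described it takes up to 4 members with the smallest p, and 8 genes were always read: SLC2A1, HK2, LALBA, B4GALT1, CSN2, FASN, TXNIP and SLC7A5. For the middle-dose test and the test of any difference it takes the 5 genes with the smallest p. Genes outside that rule (LTF, and single genes under the other observations) were chosen after their values were seen.

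Alternatives were DESeq2's size factors, library size alone, no filter, milk protein genes left out, the DESeq2 test, limma voom with quality weights, fits to only the groups compared, a replicate block, and each library left out in turn. Table layout as a term, the 8 libraries of the larger layout alone, and fry as an alternative setting were added after the data had been seen. So were leaving out milk protein genes without composition scaling, and list tests by library size alone or with milk protein genes left out. The files' own KEGG terms were tested later, for pathways of 15 to 300 genes. The edgeR step was tested on simulated counts for middle against low (13543 genes, 200 of them altered): it recovered 25% of 80 genes altered 2-fold, 73.3% of 60 altered 4-fold and 91.7% of 60 altered 8-fold, with 10 false calls of 129. With 0.5 of the estimated spread between libraries of a dose it recovered 55% of the genes altered 2-fold. Total counts were 9555072 to 12716883, and depth was not varied. Numeric doses, isoforms and sequence variants were not analysed here.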

Results

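RNA from mammary gland biopsies of lactating dairy goats was sequenced after glucose had been infused at a low, a middle or a high dose. There were 12 libraries, 4 at each dose, and each was a table of read counts per gene. The numeric doses are not given in the sources used here, and no library from an uninfused gland was analysed here. Every comparison was therefore between doses. Counts over the 15810 genes listed for all libraries totalled 9555072 to 12716883 per library. The means were 10963922 ± 602208 (SD, n = 4) at the low dose, 10588199.5 ± 1012986 at the middle dose and 11742303.75 ± 1057825 at the high dose. The totals did not differ by exact permutation tests (two-sided, high against low p = 0.229, middle against low p = 0.543, high against middle p = 0.171). Nothing in the labels says that the 4 libraries of a dose came from separate goats, so p-values measure only the spread between these samples, which may be technical. No pair of libraries matched within sampling noise, and all 12 were kept as separate samples.

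Transcripts of the milk proteins, which the secretory epithelium of the lactating gland makes in bulk, took very different shares of the libraries. The 9 milk protein genes made up 43.1 ± 26.6% (SD, n = 4) of the counts at the middle dose, 19.9 ± 16.0% at the high dose and 7.69 ± 6.15% at the low dose. At the middle dose, replicates 1, 2 and 4 held 52.0, 57.7 and 59.0%, whereas replicate 3 held 3.44%. At the high dose the shares were 7.48, 42.1, 8.83 and 21.3% in replicates 1 to 4, and at the low dose 2.61, 2.18, 12.3 and 13.7%. On the log2 share, the exact permutation p (two-sided) was 0.0857 for middle against low (0.257 adjusted over the 3 comparisons), 0.2 for high against low (adjusted 0.3) and 0.429 for high against middle (adjusted 0.429). The smallest p that the 70 arrangements allow is 0.0286. The tables came in 2 layouts that list slightly different genes, and the means had the same order of doses in both. In the layout of 8 libraries the shares were 6.15 ± 6.51% (n = 3) at the low dose, 40.1 ± 31.7% (n = 3) at the middle dose and 25.5 ± 23.5% (n = 2) at the high dose. In the layout of 4 libraries they were 12.3% (n = 1), 52.0% (n = 1) and 14.4 ± 9.74% (n = 2). Fewer genes were detected at the middle dose (14461 ± 372, n = 4) than at the low dose (15132.5 ± 101, n = 4), with an exact permutation p = 0.0286 (adjusted 0.0857), the smallest possible. The high dose lay between (14861.75 ± 305). A gene with any read was counted, and fewer reads were left for other genes where milk transcripts took more. Middle-dose replicate 3, with 3.44% of milk protein reads, had 14996 genes, and replicates 1, 2 and 4 had 14166 to 14424. The dose was therefore not separated from the depth left for other genes.

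**Figure D1:**
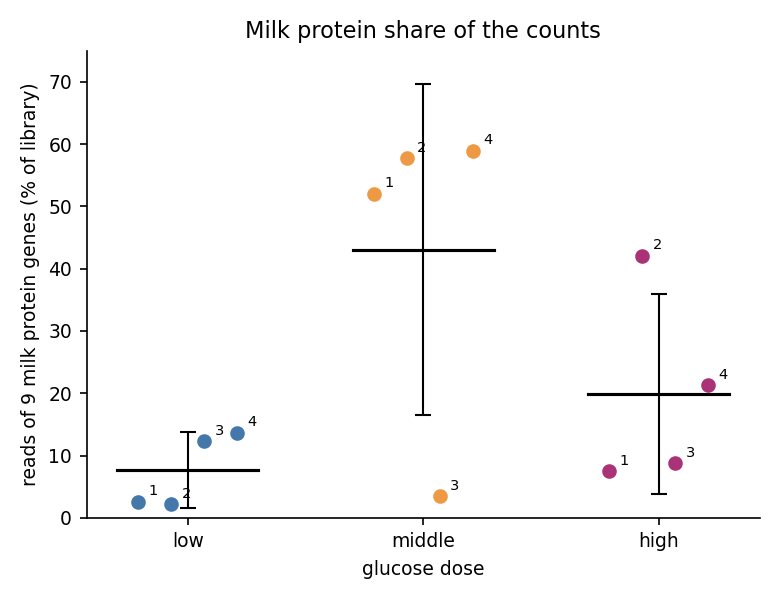
Share of each library's counts that fell on the 9 milk protein genes (y axis, percent) by glucose dose (x axis). Points are libraries numbered by replicate, lines are means and bars the SD of 4 libraries; middle-dose replicate 3, at 3.44%, sits with the low-dose libraries while the other middle-dose libraries lie between 52.0 and 59.0%.

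The first principal component of log2 CPM held 44.9% of the variance and the second 14.9%. Middle-dose replicates 1, 2 and 4 and high-dose replicate 2 lay at one end of the first component, and middle-dose replicate 3 lay at the other with low-dose replicates 1, 2 and 4 and high-dose replicate 1. Low-dose replicate 3 lay near the centre. The nearest library to middle-dose replicate 3 was low-dose replicate 2 (Spearman's rho over genes 0.981). Its mean rho was 0.954 with the low-dose libraries, 0.946 with the high-dose libraries and 0.908 with the other middle-dose libraries. Genes are not independent replicates, so these rank correlations describe the libraries only.

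**Figure D2:**
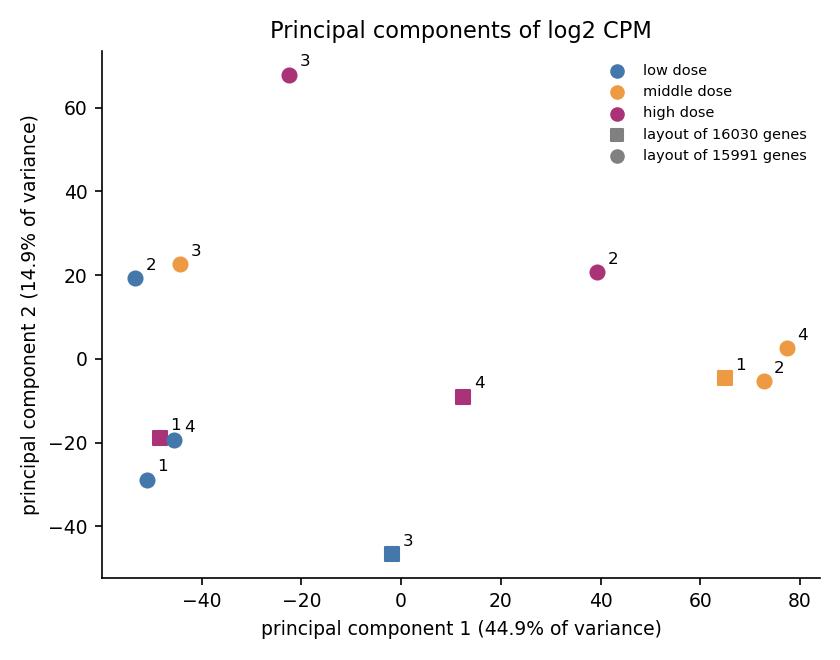
Libraries on the first (x axis, 44.9% of variance) and second (y axis, 14.9%) principal components of log2 CPM. Colours give the dose, numbers the replicate and symbols the table layout; squares and circles mix, and middle-dose replicate 3 lies on the first component with low-dose replicates 1, 2 and 4 and high-dose replicate 1.

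The high and low doses were compared to ask how gland transcripts differ between the ends of the dose range. No single gene passed, but camera at its preset correlation called 16 of 37 gene lists fixed in advance, 13 higher and 3 lower at the high dose. With an estimated correlation it called 0, and fry called 0. The endoplasmic reticulum chaperone list holds chaperones, which fold proteins bound for secretion, and genes of the unfolded protein response such as XBP1. All 18 measured genes in it had higher estimates at the high dose (median log2 0.61, camera adjusted p = 1.65e-09, adjusted p = 0.472 with an estimated correlation). Of these, 9 passed when adjusted over the list alone. XBP1, a transcription factor of the unfolded protein response, was 3.74-fold higher (518.6 ± 403 against 139 ± 14.5 CPM, SD, n = 4 each), with values from 153 CPM in high-dose replicate 1 to 1077 CPM in replicate 3. HSPA5, the main chaperone of the compartment, was 2.08-fold higher (log2 1.05 ± 0.31 SE), and CRELD2 (1.17 ± 0.33) and PDIA4 (0.65 ± 0.20) were among the 9. In the cholesterol synthesis list 16 of 17 genes were higher (median 1.02, adjusted p = 8.74e-08, adjusted p = 0.472 with an estimated correlation). Past the threshold when adjusted over the list alone were 7, and they included MVD (1.57 ± 0.44) and LSS (1.33 ± 0.45).

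Lists of mitochondrial and lipid metabolism were also higher at the high dose. Of 23 genes of pyruvate dehydrogenase and the TCA cycle, 20 were higher (median 0.34, camera adjusted p = 1.30e-05, adjusted p = 0.472 with an estimated correlation). Over the list alone OGDH (0.55 ± 0.16) and CS (0.69 ± 0.20) passed upward and IDH2 (-0.78 ± 0.20) downward. Of 33 nuclear genes of oxidative phosphorylation, 31 were higher by a small margin (median 0.23, adjusted p = 4.11e-05, adjusted p = 0.574 with an estimated correlation), and 0 passed over the list alone. That median was 0.14, 0.15 and 0.34 without high-dose replicates 2, 3 and 4. Triglyceride synthesis and fat globule secretion had 13 of 14 genes higher (median 0.92, adjusted p = 0.000252, adjusted p = 0.472 with an estimated correlation). AGPAT6, which adds a fatty acid to glycerol phosphate, stood at 2.04 ± 0.69 and CIDEA, a lipid droplet protein, at 2.70 ± 0.98, neither past the threshold. In fatty acid synthesis and uptake 14 of 18 were higher (median 0.88, adjusted p = 0.00176, adjusted p = 0.472 with an estimated correlation). The heart-type fatty acid binding protein gene H-FABP stood at 3.78 ± 1.03 and SREBF1 at 1.18 ± 0.37, both short of the threshold over the list alone. Heat shock genes were higher in 11 of 12 cases (median 0.67, adjusted p = 0.000968, adjusted p = 0.472 with an estimated correlation), and HSPH1 (1.61 ± 0.44) passed over the list alone. Without high-dose replicate 3 the median of the list was 0.30. The integrated stress response list (13 of 16 higher, median 0.85, adjusted p = 0.00414, adjusted p = 0.574 with an estimated correlation) was led by CHAC1 (3.82 ± 1.18) and ATF4 (1.33 ± 0.44). The AMPK and mTOR list (23 of 26 higher, median 0.17, adjusted p = 0.00388, adjusted p = 0.472 with an estimated correlation) was led by PRKAA2 (1.19 ± 0.36), and its median was 0.28 without high-dose replicate 1.

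T and NK cell markers, interferon response genes and the cell cycle went the other way, and the other immune lists were not called. Of 14 T and NK cell markers, 13 were lower at the high dose (median -0.80, camera adjusted p = 2.00e-07, adjusted p = 0.472 with an estimated correlation). CD4, the helper T cell co-receptor, was 2.62-fold lower (2.87 ± 0.747 against 7.57 ± 4.09 CPM) and alone passed over the list. All 17 interferon response genes were lower (median -1.60, adjusted p = 7.79e-05, adjusted p = 0.574 with an estimated correlation). Over the list alone 12 of them were past the threshold, among them ISG15 (-2.88 ± 1.03), IFI44 (-1.33 ± 0.46) and CMPK2 (-1.63 ± 0.57). This list was set by low-dose replicate 4. Its mean log2 CPM was 6.83 there and 3.43 to 4.61 in the other 11 libraries, and without that library the median was -0.34 and the adjusted p 0.0517. Cell cycle genes were lower in 21 of 22 cases by a small margin (median -0.27, adjusted p = 0.00461, adjusted p = 0.707 with an estimated correlation). The call was lost without high-dose replicate 2 (0.267), high-dose replicate 4 (0.277) or low-dose replicate 2 (0.0851) and with a replicate block (0.115). The median turned to 0.032 and 0.035 without high-dose replicates 2 and 4, and was -1.11 and -0.44 without high-dose replicates 1 and 3 and -0.12 and -0.45 without low-dose replicates 2 and 3.

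The secretory lists of the gland were higher at the high dose with calls that single libraries decided. All 9 milk protein genes were higher (median 1.49, camera adjusted p = 0.00692, adjusted p = 0.574 with an estimated correlation), 0 of them past the threshold over the list alone. That call was lost without high-dose replicate 2 (0.0529), high-dose replicate 4 (0.0650) or low-dose replicate 2 (0.0918). The median was 0.67 without high-dose replicate 2 and 2.53 without low-dose replicate 3. Glucose uptake and lactose synthesis had 10 of 14 genes higher (median 0.41, adjusted p = 0.0271, adjusted p = 0.472 with an estimated correlation). Over the list alone B4GALT1, the galactosyltransferase of lactose synthase (1.14 ± 0.31), and SLC35A2, which carries UDP-galactose into the Golgi (1.39 ± 0.36), passed. This list's p was 0.0537 without high-dose replicate 4 and 0.0558 with the milk protein genes left out, and its median was 0.13 without high-dose replicate 3. Amino acid transporters (16 of 23 higher, median 0.26, adjusted p = 0.0263, adjusted p = 0.472 with an estimated correlation), were led by SLC1A5 (2.06 ± 0.58). They lost the call without high-dose replicate 2 (0.0526), high-dose replicate 4 (0.0537) or low-dose replicate 2 (0.0913), with table layout as a term (0.0743) and with a replicate block (0.05004). Their median was 0.46 and 0.15 without high-dose replicates 1 and 2 and 0.16 and 0.55 without low-dose replicates 1 and 3. Prolactin and STAT5 signalling (6 of 11 higher, median 0.52, adjusted p = 0.0355, adjusted p = 0.472 with an estimated correlation), held CISH, a feedback inhibitor of cytokine receptors, which passed over the list alone (1.54 ± 0.32). The list lost its call without high-dose replicate 2 (0.0913), high-dose replicate 4 (0.182) or low-dose replicate 3 (0.135), with table layout as a term (0.0623) and with a replicate block (0.0506). Its median was 0.080 without high-dose replicate 2.

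Of the 13624 genes tested, 0 passed an adjusted p of 0.05 by edgeR, against 1560 at unadjusted p under 0.05 (990 higher, 570 lower), 51 by DESeq2 (37 higher, 14 lower) and 0 by limma voom with quality weights. The 10 genes with a symbol and the smallest p all had an edgeR adjusted p of 0.386. The arginase gene ARG2 was 14.8-fold higher at the high dose (52.3 ± 38.9 against 3.50 ± 0.332 CPM, n = 4 each) and the Wnt receptor gene FZD5 11.8-fold higher (11.96 ± 11.3 against 1.00 ± 0.158 CPM). The log2 difference of FZD5 was 3.56, and 2.69 without high-dose replicate 2. THBD (thrombomodulin, log2 1.51 ± 0.29), CISH, the magnesium transporter gene SLC41A1 (2.42 ± 0.54) and MOGS, which trims N-glycans (1.08 ± 0.24), were higher. Lower were CROT (-1.60 ± 0.35), BCAR3 (-0.87 ± 0.19) and SIDT1 (-0.93 ± 0.21). Counts of calls depended on the libraries. Without high-dose replicate 1 edgeR called 19 genes (18 higher, 1 lower), ARG2 with adjusted p = 0.00241 among them. It called 8 (all higher) within the 8 libraries of the larger layout. At 644 genes (4.73%) the 4 libraries of one dose all lay above those of the other, against a chance share of 2.86%. That share is the mean over arrangements. Genes vary together, and the spread of the share over splits was not computed, so an excess was not tested.

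The middle and low doses were compared to ask what an intermediate glucose supply did relative to the smallest. No single gene passed, but camera at its preset correlation called 23 of the 37 lists, 14 higher and 9 lower at the middle dose. It called 0 with an estimated correlation and 15 by library size alone. The directional test of fry called 0, and its mixed test, which lets members of a list move either way, called 21 (0 in the other comparisons of doses). Of 9 milk protein genes 8 had higher estimates (median log2 4.24; camera adjusted p = 0.000526, adjusted p = 0.312 with an estimated correlation). Adjusted over the list alone, 7 passed upward, among them the beta-casein gene CSN2 (19.0-fold, 4.24 ± 1.39 SE), the alpha-lactalbumin gene LALBA (46.6-fold, 5.54 ± 1.68), CSN1S1 (5.18 ± 1.73) and PAEP (2.55 ± 0.78). The lactoferrin gene LTF passed downward (-2.96 ± 1.18), a call lost without middle-dose replicate 3 (-2.76 ± 1.34). Triglyceride synthesis and fat globule secretion (12 of 14 higher, median 1.69, adjusted p = 2.61e-05, adjusted p = 0.267 with an estimated correlation) had 9 genes past the threshold over the list alone. They included MFGE8, a protein of the fat globule membrane (2.56 ± 0.53), AGPAT6 (2.90 ± 0.71), LPAAT (1.47 ± 0.37) and the lipid droplet gene PLIN2 (1.83 ± 0.47). Fatty acid synthesis and uptake (14 of 18 higher, median 1.202, adjusted p = 0.000270, adjusted p = 0.267 with an estimated correlation) also had 9. Among these were ACACA and FASN, the enzymes of fatty acid synthesis (2.20 ± 0.52 and 2.30 ± 0.58), H-FABP (4.27 ± 1.06) and the fatty acid translocase gene CD36 (2.83 ± 0.74).

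Lists of cholesterol synthesis, the integrated stress response, amino acid use and oxidative phosphorylation were higher with them. All 17 cholesterol synthesis genes were higher (median 1.03, camera adjusted p = 1.86e-05, adjusted p = 0.312 with an estimated correlation). Of these 4 were past the threshold over the list alone, LSS (1.57 ± 0.45) and FDFT1 (1.00 ± 0.31) among them. The integrated stress response list, which holds serine and asparagine synthesis genes controlled by ATF4, was higher in 14 of 16 cases (median 1.58, adjusted p = 0.000178, adjusted p = 0.312 with an estimated correlation), 8 past the threshold over the list alone. These included ATF5 (9.13-fold, 122.8 ± 87.1 against 13.4 ± 2.13 CPM), PSPH (8.20-fold), PSAT1 (6.24-fold) and MTHFD2 (4.05-fold). Amino acid transporters (16 of 23 higher, median 0.67, adjusted p = 0.00596, adjusted p = 0.267 with an estimated correlation) had 8 such genes. In front were SLC1A5 (2.53 ± 0.59), SLC1A2 (3.09 ± 0.74), SLC1A4 (1.83 ± 0.45) and SLC7A5 (2.74 ± 0.71). In branched-chain amino acid breakdown 14 of 20 were higher (median 0.27, adjusted p = 0.00368, adjusted p = 0.267 with an estimated correlation). Over the list alone 6 passed upward, BCKDK (0.81 ± 0.19) and HIBADH (0.95 ± 0.24) among them, and 1 downward. Oxidative phosphorylation was higher in 32 of 33 genes (median 0.34, adjusted p = 2.56e-06, adjusted p = 0.312 with an estimated correlation), led by NDUFA6 (0.70 ± 0.19).

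Several lists of signalling were higher by smaller margins. In prolactin and STAT5 signalling 9 of 11 genes were higher (median 0.43, camera adjusted p = 0.00607, adjusted p = 0.267 with an estimated correlation). ELF5, the transcription factor of alveolar differentiation, passed over the list alone (1.65 ± 0.40). AMPK and mTOR signalling (22 of 26 higher, median 0.33, adjusted p = 0.000270, adjusted p = 0.267 with an estimated correlation) was led by CAMKK2 (1.42 ± 0.32). Insulin and IGF signalling (11 of 16 higher, median 0.19, adjusted p = 0.0319, adjusted p = 0.267 with an estimated correlation) was led by FOXO3 (0.77 ± 0.19) and IRS1 (1.204 ± 0.31). Its call was lost without low-dose replicate 2 (0.0802) or middle-dose replicate 1 (0.0606) and with a replicate block (0.0687). Endoplasmic reticulum chaperones were higher in 15 of 18 cases (median 0.35, adjusted p = 0.0165, adjusted p = 0.400 with an estimated correlation), 0 of them past the threshold over the list alone. They lost the call without low-dose replicate 2 (0.0521) or middle-dose replicate 3 (0.0935). Without middle-dose replicate 3 the call was also lost by pyruvate dehydrogenase and the TCA cycle (19 of 23 higher, median 0.28, adjusted p = 0.00407, adjusted p = 0.405 with an estimated correlation, 0.0881 without the library). In it IDH2 (-1.07 ± 0.20) and IDH3A (-0.92 ± 0.20) were lower. The same held for the glucose-responsive ChREBP targets (7 of 9 lower, median -0.51, adjusted p = 0.0264, adjusted p = 0.267 with an estimated correlation, 0.0881 without the library), with KLF10 at -1.57 ± 0.32 and ARRDC4 at -0.91 ± 0.21.

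Glycolysis, the cell cycle, apoptosis and involution genes, interferon response genes, MHC class II genes and macrophage, T and NK cell and fibroblast markers were lower at the middle dose. Neutrophil, B and plasma cell and inflammation lists were not called. Of 16 glycolysis genes 13 were lower (median -0.53, camera adjusted p = 0.000240, adjusted p = 0.267 with an estimated correlation). Past the threshold over the list alone were 6, with the lactate dehydrogenase gene LDH-A at -1.26 ± 0.22, GAPDH at -0.87 ± 0.20 and TPI1 at -0.78 ± 0.24. All 22 cell cycle genes were lower (median -1.54, adjusted p = 1.11e-05, adjusted p = 0.382 with an estimated correlation). CCNA2 was lower by 0.79 ± 0.31 and MCM3 by 1.21 ± 0.49 on the log2 scale, with 0 genes past the threshold over the list alone. The median of the list was -3.93 without middle-dose replicate 3. All 10 macrophage markers were lower (median -0.91, adjusted p = 0.000173, adjusted p = 0.267 with an estimated correlation), 9 past the threshold over the list alone, such as FCER1G (-1.11 ± 0.24) and AIF1 (-1.03 ± 0.23). All 14 T and NK cell markers were lower (median -0.78, adjusted p = 5.58e-05, adjusted p = 0.267 with an estimated correlation), 7 past it, CD4 in front (-1.76 ± 0.37). So were 6 of 7 MHC class II antigen presentation genes (median -1.03, adjusted p = 0.00154, adjusted p = 0.267 with an estimated correlation), 5 past it, such as CTSS (-1.03 ± 0.24). All 17 interferon response genes were lower (median -1.51, adjusted p = 0.000241, adjusted p = 0.407 with an estimated correlation), 15 past the threshold over the list alone. Low-dose replicate 4 set the size of that difference. Without it the median was -0.39, with an adjusted p of 0.00369. All 12 fibroblast markers (median -0.75, adjusted p = 0.00121, adjusted p = 0.370 with an estimated correlation) and 16 of 20 apoptosis and involution genes (median -0.42, adjusted p = 0.00918, adjusted p = 0.267 with an estimated correlation) were lower. COL6A1 stood at -0.83 ± 0.31 and the clusterin gene CLU at -2.67 ± 0.72, with 0 past the threshold over either list alone. The fibroblast median was -0.42 without low-dose replicate 4. Endothelial markers alone among the markers of other cell types were called higher (9 of 9, median 0.72, adjusted p = 0.000270, adjusted p = 0.267 with an estimated correlation). Of these 6 passed over the list alone, with ESAM at 0.94 ± 0.25 and KDR, the VEGF receptor, at 1.01 ± 0.28.

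Of the 13624 genes, 0 passed an adjusted p of 0.05 by edgeR, against 3234 at unadjusted p under 0.05 (1697 higher, 1537 lower), 1396 by DESeq2 (815 higher, 581 lower) and 4701 by limma voom with quality weights (2312 higher, 2389 lower), which gave middle-dose replicate 3 a weight of 0.323. Middle-dose replicate 3 decided the count. Without it edgeR called 2390 of 13797 genes (1199 higher, 1191 lower), 857 of them under 2-fold. Of the 2390, 1229 were also called by DESeq2 on all 12 libraries. Without low-dose replicate 2 edgeR called 16 genes, and without middle-dose replicate 2 it called 1. The 10 genes with a symbol and the smallest p all had an edgeR adjusted p of 0.0735 on all libraries. NUDT12, which hydrolyses NADH, was 6.29-fold higher at the middle dose (249 ± 102 against 39.6 ± 14.6 CPM, n = 4 each) and the folate-retaining enzyme gene FPGS 2.03-fold higher (57.1 ± 7.27 against 28.2 ± 5.88 CPM). REC8 (1.42 ± 0.23), SPATA13 (1.55 ± 0.26), CDK2AP2 (1.13 ± 0.20) and MTIF3 (1.10 ± 0.19) were also higher. Lower were LDH-A (26.4 ± 1.94 against 63.3 ± 18.5 CPM), the interferon receptor gene IFNAR2 (-1.02 ± 0.17), DOCK10 (-0.91 ± 0.16) and HMHA1 (-0.91 ± 0.16). Without middle-dose replicate 3 all 10 passed, NUDT12 with adjusted p = 0.00475 and LDH-A with 0.0116. The 10 were picked by p in these same data, and that library was singled out because it lay apart from its dose. These values are therefore no further support. Over all libraries 1614 genes (11.8%) had no overlap between the doses, against a chance share of 2.86%. The spread of that share over splits was not computed, so an excess was not tested.

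Without middle-dose replicate 3, 20 lists were called by camera and 18 by fry, but 0 by camera with an estimated correlation (smallest adjusted p = 0.237). In that set 19 of 22 cell cycle genes fell past the threshold over all genes (median log2 -3.93) and 7 of 9 milk protein genes rose (median 4.65). In the integrated stress response list 8 of 16 rose, in cholesterol synthesis 10 of 17, in triglyceride synthesis 8 of 14 and in fatty acid synthesis and uptake 8 of 18, while 2 of the 18 fell. Of 16 glycolysis genes and of 10 macrophage markers 6 each fell, and 6 of 9 endothelial markers rose. These calls, and those without that library in the other tests, rest on leaving out a library seen to lie apart from its dose. No splits were run without it, so chance was not weighed for them.

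**Figure D3:**
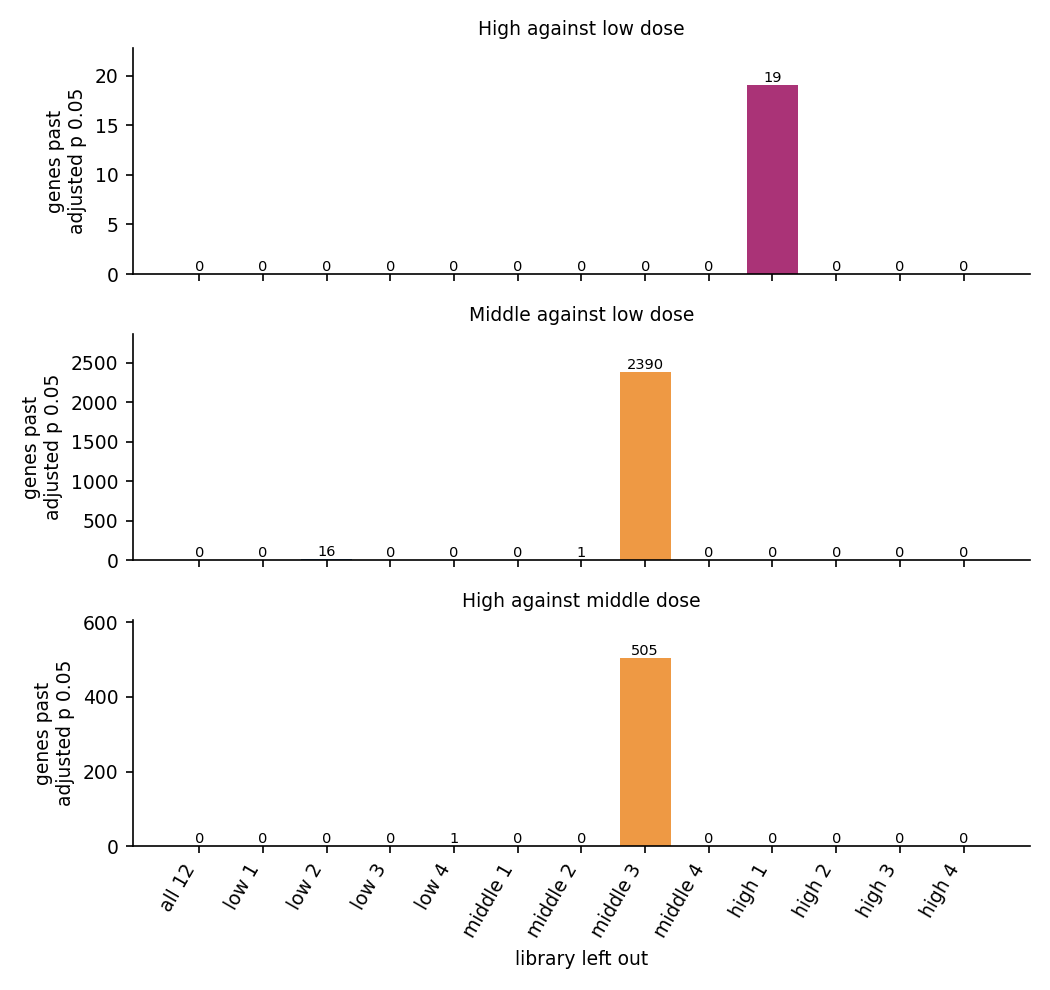
Number of genes past an adjusted p of 0.05 by edgeR (y axis, its range differs between panels) with all 12 libraries and with each library left out in turn (x axis), for the 3 comparisons of doses. Bars are coloured by the dose of the library left out; leaving out middle-dose replicate 3 gave 2390 genes for middle against low and 505 for high against middle.

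The high and middle doses were compared to ask whether the larger dose went beyond the middle one. No single gene passed, but camera at its preset correlation called 10 of the 37 lists, 8 higher and 2 lower at the high dose. It called 0 with an estimated correlation and fry called 0, and 21 of the 35 splits of these 8 libraries gave at least 10. The balance depended on scaling and libraries, with 8 higher and 8 lower by library size alone. It was 9 and 6 without middle-dose replicate 3, 10 and 7 without high-dose replicate 2 and 11 and 7 without high-dose replicate 3. Of 16 glycolysis genes 14 were higher at the high dose (median log2 0.47; camera adjusted p = 6.58e-05, adjusted p = 0.516 with an estimated correlation). LDH-A (0.97 ± 0.22 SE), TPI1 (0.93 ± 0.24) and GAPDH (0.68 ± 0.20) passed when adjusted over the list alone. All 12 heat shock genes were higher (median 0.68, adjusted p = 0.000877, adjusted p = 0.543 with an estimated correlation). DNAJB1 passed over the list alone (0.81 ± 0.22), and HSPH1 stood at 1.31 ± 0.44. The median was 0.43 without high-dose replicate 3. Endoplasmic reticulum chaperones were higher in 13 of 18 cases (median 0.43, adjusted p = 0.00420, adjusted p = 0.646 with an estimated correlation), MANF passing over the list alone (1.31 ± 0.34). Without high-dose replicate 3 the median was 0.28 and the adjusted p 0.0844. All 22 cell cycle genes were higher (median 1.16, adjusted p = 0.000877, adjusted p = 0.690 with an estimated correlation), CCNA2 by 0.67 ± 0.31. Over the list alone 0 passed, and without high-dose replicate 1 the list's median was 0.37 and its adjusted p 0.0865. Without middle-dose replicate 3 the median was 3.41.

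Macrophage, neutrophil, MHC class II and apoptosis lists were higher at the high dose as well, while T and NK cell and B and plasma cell markers were not called. All 10 macrophage markers (median 0.56, camera adjusted p = 0.00410, adjusted p = 0.646 with an estimated correlation) were higher, 0 past the threshold over the list alone, with CD68 at 1.02 ± 0.37. Their median was 0.85 without middle-dose replicate 3. All 8 neutrophil markers were higher (median 1.32, adjusted p = 0.00935, adjusted p = 0.646 with an estimated correlation). The 4 that passed over the list alone were the calgranulin genes S100A9 (2.50 ± 0.68), S100A12 (2.66 ± 0.82) and S100A8 (2.58 ± 0.90), and CXCR1 (1.76 ± 0.66). S100A9 stood at 17.5 CPM in high-dose replicate 3 and at 2.19 to 5.07 CPM in the other high-dose libraries. The list's adjusted p was 0.0735 without middle-dose replicate 3 and 0.0946 by library size alone. Of 7 MHC class II genes 6 were higher (median 0.53, adjusted p = 0.0396, adjusted p = 0.646 with an estimated correlation), led by CTSS (0.64 ± 0.24). The call was lost without high-dose replicates 2 (0.0738) or 4 (0.163) or middle-dose replicates 2 (0.0684) or 4 (0.0903), with table layout as a term (0.0755), by library size alone (0.0954), and by library size with the milk protein genes left out (0.0639). Their median was 0.84 without middle-dose replicate 3. Apoptosis and involution genes were higher in 16 of 20 cases (median 0.54, adjusted p = 0.00661, adjusted p = 0.516 with an estimated correlation). BCL2 stood at 1.11 ± 0.38 and SOCS3, a STAT3 target of the involuting gland, at 1.54 ± 0.53. All 9 endothelial markers were lower (median -0.61, adjusted p = 0.000428, adjusted p = 0.543 with an estimated correlation), 4 past the threshold over the list alone, such as EMCN (-0.66 ± 0.17). So were 15 of 20 genes of branched-chain amino acid breakdown (median -0.25, adjusted p = 0.00626, adjusted p = 0.516 with an estimated correlation), ALDH6A1 in front (-0.55 ± 0.17). This call was lost without high-dose replicate 4 (0.0576) or middle-dose replicate 3 (0.0606, median -0.13) and by library size alone (0.0954).

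Of the 13624 genes, 0 passed an adjusted p of 0.05 by edgeR, against 2029 at unadjusted p under 0.05 (1021 higher, 1008 lower), 257 by DESeq2 (114 higher, 143 lower) and 859 by limma voom with quality weights (460 higher, 399 lower). Without middle-dose replicate 3 edgeR called 505 genes (235 higher, 270 lower), 159 of them under 2-fold and 168 also called by DESeq2 on all 12 libraries. Without low-dose replicate 4 it called 1. The 10 genes with a symbol and the smallest p had an edgeR adjusted p of 0.196. F3, the tissue factor gene, was 3.91-fold higher at the high dose (90.5 ± 22.2 against 23.2 ± 2.61 CPM, n = 4 each), and CCL2, a monocyte chemokine, 7.43-fold higher (29.2 ± 13.4 against 3.82 ± 2.41 CPM). TNFRSF12A (2.60 ± 0.49), RARRES1 (1.74 ± 0.33), TUBB6 (1.22 ± 0.20), SYNJ2 (1.16 ± 0.21) and EPHA2 (1.00 ± 0.17) were higher. ASCC1 (-0.9998 ± 0.16), UBXN7 (-0.81 ± 0.14) and FPGS (-0.96 ± 0.17) were lower. Over all libraries 809 genes (5.94%) had no overlap between the doses, against a chance share of 2.86%, and an excess was again not tested over splits. Without middle-dose replicate 3, 15 lists were called by camera, 2 by fry (glycolysis and endothelial markers) and 0 by camera with an estimated correlation (smallest adjusted p = 0.386). In that set 7 of 22 cell cycle genes rose and 3 of 9 endothelial markers fell past the threshold over all genes.

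**Figure D4:**
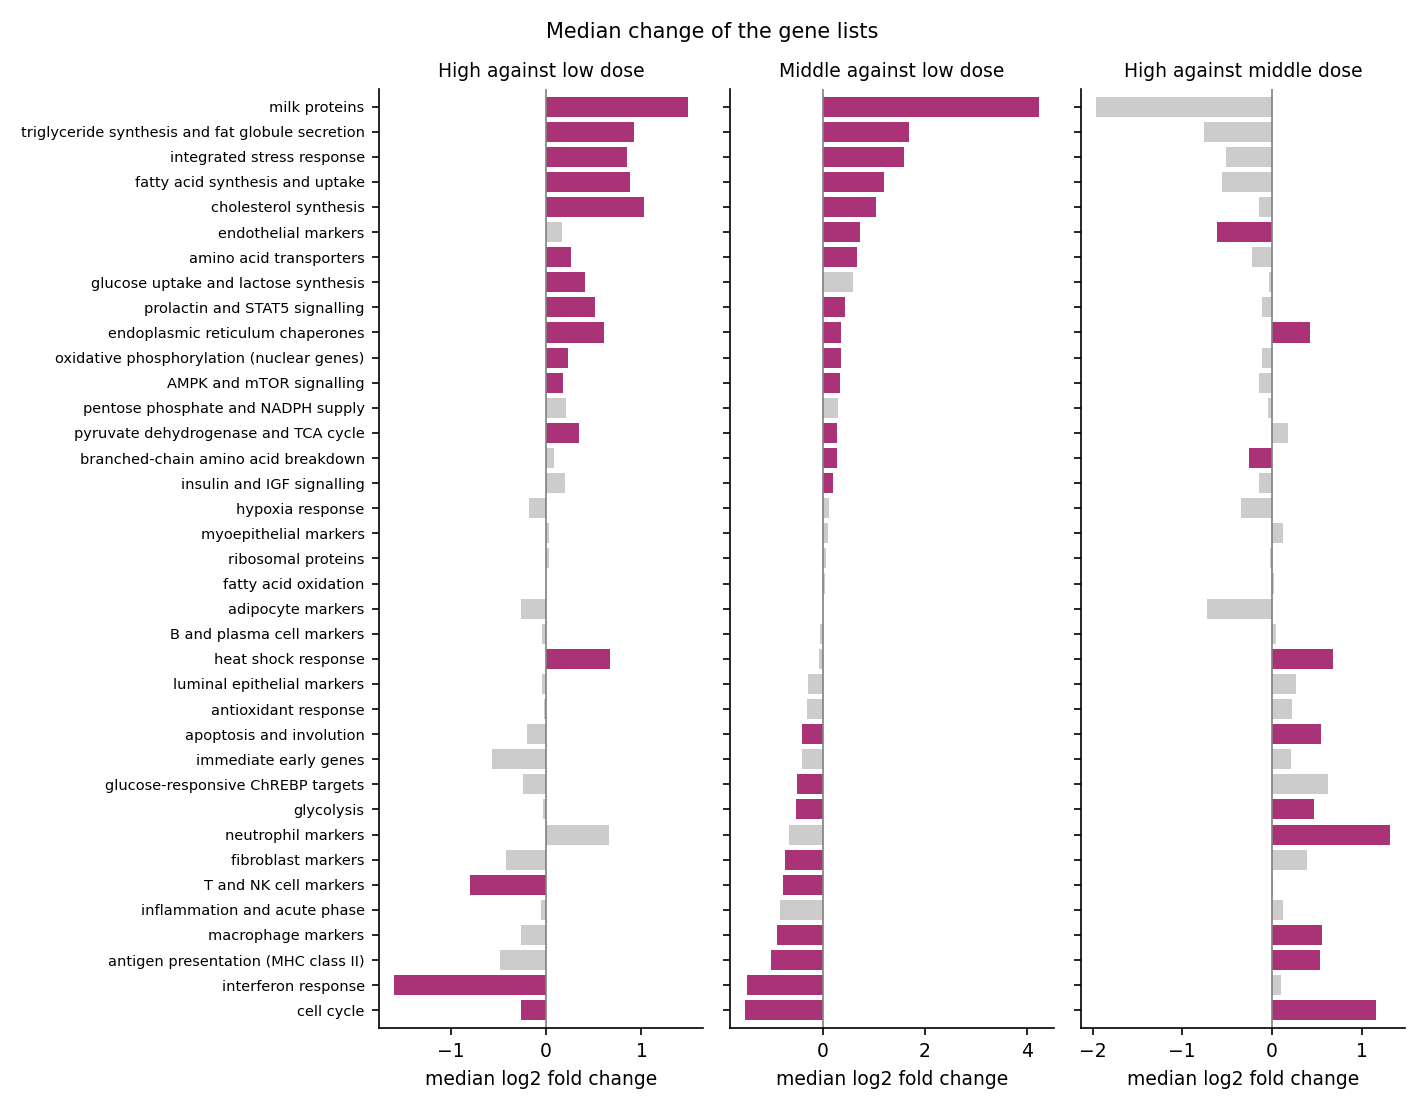
Median log2 fold change (x axis, its range differs between panels) of the 37 gene lists (y axis) in the 3 comparisons of doses, coloured where camera with a preset correlation gave an adjusted p under 0.05 (16, 23 and 10 lists) and grey otherwise. Values are scaled by TMM. With library size alone the median of all genes moved to -0.32, -0.86 and 0.56. Relative to it all coloured lists kept their direction, which rescaling all genes of a library alike nearly ensures.

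The direction of a list was relative to all genes. Scaling by library size alone moved the median log2 of all genes to -0.32 for high against low, -0.86 for middle against low and 0.56 for high against middle, from -0.03, -0.03 and 0.03 with TMM. Relative to that median all 16, 23 and 10 called lists kept their direction. This was nearly fixed in advance, because rescaling a library moves all its genes alike. The list's own median, however, changed sign in 3 for high against low (oxidative phosphorylation, amino acid transporters, and AMPK and mTOR signalling). It changed sign in 10 for middle against low (TCA cycle, oxidative phosphorylation, cholesterol synthesis, amino acid transporters, branched-chain amino acid breakdown, AMPK and mTOR, insulin and IGF, prolactin and STAT5, chaperones and endothelial markers), and in 2 for high against middle (endothelial markers and branched-chain amino acid breakdown). With library size alone camera kept the call of 16 of 16, 14 of 23 and 7 of 10 of these lists. For middle against low the 9 lost were the TCA cycle, oxidative phosphorylation, branched-chain amino acid breakdown, AMPK and mTOR, insulin and IGF, ChREBP targets, chaperones, MHC class II and fibroblast markers. For high against middle the 3 lost were branched-chain amino acid breakdown, MHC class II and neutrophil markers.

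The genes chosen in advance for the question of glucose use were read in all 3 comparisons. SLC2A1, the basal glucose transporter (chromosome 3, 99532153 to 99548625 in the files' coordinates), stood at 27.8 ± 12.01, 61.6 ± 28.9 and 67.4 ± 26.1 CPM at the low, middle and high doses (SD, n = 4 each). Its log2 differences were 1.28 ± 0.46 (SE) for high against low (edgeR adjusted p = 0.386) and 1.14 ± 0.46 for middle against low (0.165). The latter passed at 1.45 (adjusted p = 0.0228) without middle-dose replicate 3. HK2 (chromosome 11, 9581412 to 9649463), which phosphorylates glucose, stood at 14.8 ± 8.96, 10.01 ± 9.15 and 26.1 ± 23.2 CPM. Its log2 differences were 0.82 ± 0.67, -0.52 ± 0.68 and, for high against middle, 1.34 ± 0.68, none past the threshold. Single libraries moved these, to -0.024 without high-dose replicate 3 and 1.28 without low-dose replicate 2 for high against low. They were -0.066 without low-dose replicate 2 and -1.42 without middle-dose replicate 3 for middle against low, and 0.50 without high-dose replicate 3 and 2.25 without middle-dose replicate 3 for high against middle. TXNIP (chromosome 3, 19556095 to 19560269), which glucose induces in many cell types, did not pass, at -0.25 ± 0.43 (high against low), 0.24 ± 0.43 (middle against low) and -0.49 ± 0.43 (high against middle). Its values without high-dose replicate 4 were -0.69 (high against low) and -0.97 (high against middle), and without high-dose replicate 3 -0.0011 and -0.25. For middle against low they ranged from 0.028 without low-dose replicate 2 to 0.43 without middle-dose replicate 3. B4GALT1 (chromosome 8, 73062034 to 73110865) stood at 351 ± 93.3, 942 ± 244 and 771 ± 260.3 CPM. LALBA (chromosome 5, 30098673 to 30100689), whose protein completes lactose synthase, stood at 959.7 ± 1244, 44693 ± 30461 and 8981 ± 12529 CPM. CSN2 (chromosome 6, 82704636 to 82713707) stood at 22664 ± 20259, 429449.7 ± 292382 and 113499 ± 133957 CPM. For these 3 genes and for FASN (chromosome 19, 49715750 to 49732977) and the leucine transporter gene SLC7A5 (chromosome 18, 12790420 to 12817098) the edgeR adjusted p on all libraries was 0.0735 to 0.109 for middle against low. All 5 rose without middle-dose replicate 3 (SLC7A5 log2 3.13 at edgeR adjusted p = 0.00493, B4GALT1 1.58 at 0.0104, FASN 2.55 at 0.0158, CSN2 4.65 at 0.0232 and LALBA 5.95 at 0.0237). That library was singled out after its values were seen, so these p-values are not independent support. Between the high and middle doses none of the 8 passed with or without that library.

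**Figure D5:**
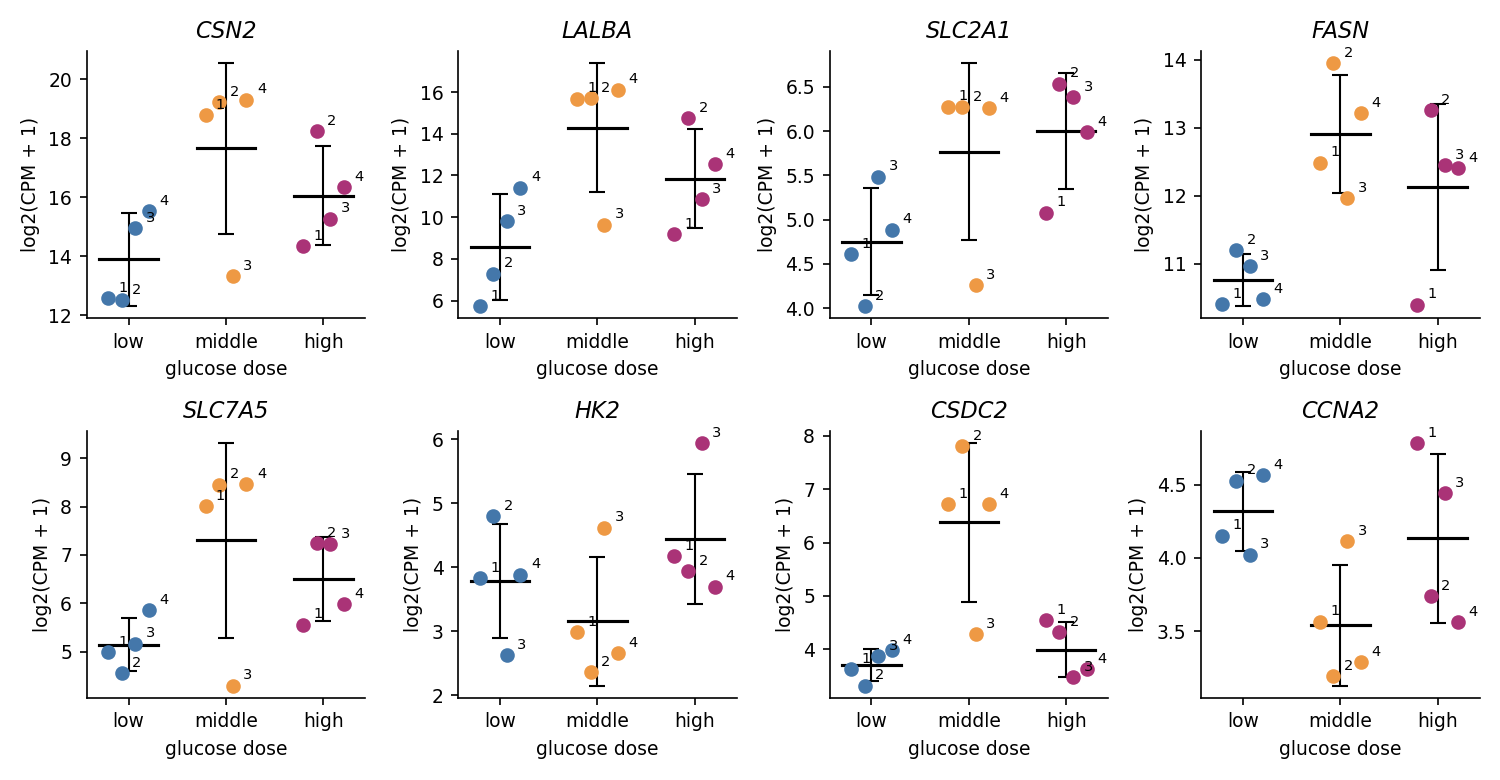
Levels of 8 genes as log2(CPM + 1) (y axes, ranges differ) by glucose dose (x axes). Points are libraries numbered by replicate, lines are means and bars the SD of 4 libraries; SLC2A1, SLC7A5, CSN2 and LALBA in middle-dose replicate 3 lie far below the other middle-dose libraries.

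The doses are ordered, and the middle dose was set against the mean of the other 2 to ask whether the response turned there. CSDC2, an RNA-binding protein gene, led this test and the test of any difference among doses. It stood at 113 ± 84.1 CPM at the middle dose, 12.2 ± 2.60 at the low and 15.7 ± 5.88 at the high dose (n = 4 each), log2 3.02 ± 0.44 above their mean (edgeR adjusted p = 0.0634). FPGS (0.99), REC8 (1.22) and the collagen receptor gene DDR2 (0.94 ± 0.15) followed upward and F3 (-1.65 ± 0.27) downward, with the same adjusted p. In the test of any difference CSDC2, FPGS, REC8, F3 and ASCC1 came first, with an adjusted p of 0.130. By edgeR 0 genes passed the test of the middle dose, against 2989 at unadjusted p under 0.05 (1649 higher, 1340 lower), 1027 by DESeq2 (618 higher, 409 lower) and 4169 by limma voom with quality weights. With edgeR 2170 passed without middle-dose replicate 3 (1136 higher, 1034 lower), 10 without low-dose replicate 2 and 1 without middle-dose replicate 2. For any difference among doses 0 passed by edgeR, against 2913 at unadjusted p under 0.05, 1083 by DESeq2 and 3839 by limma voom with quality weights. With edgeR 1289 passed without middle-dose replicate 3, 3 without high-dose replicate 1 and 1 without middle-dose replicate 2.

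The changes from the low dose to the middle and to the high dose were correlated over the 13624 genes (Pearson's r = 0.640), a correlation across genes, which are not independent replicates. Both changes share the low-dose libraries. With no effect and shared libraries, 30 simulations gave a mean r of 0.488 and at most 0.525. With the low-dose libraries split between the comparisons the mean over 6 splits was 0.374 (0.302 to 0.474). The covariance was 0.264, against 0.0882 simulated, a difference of 0.176, and 0.186 with the split libraries. These simulations hold no structure between libraries of a dose. Of 100 groupings of the 12 libraries, 99 drawn at random and the real one, 26 gave an r at least as high, up to 0.812. Leaving out high-dose replicate 2 gave r = 0.497, leaving out middle-dose replicate 3 0.533 and leaving out low-dose replicate 3 0.703.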

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

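Both tests of exchanged samples, the test of endothelial against macrophage markers and the test without milk protein genes and composition scaling were chosen after the result was seen. So were the splits counted at unadjusted p or by correlation, and table layout as a term, while the other tests in this part were chosen before. Values below stand alone from the other 3 libraries of their dose by Dixon's test at the 95% critical value for 4 samples. Of 237 groups of 4 values tested, 21 did so, where chance gives about 11.9, and 14 of the 21 were in middle-dose replicate 3.

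Milk transcripts in middle-dose replicate 3 were low: the milk protein share was 3.44% against 52.0 to 59.0% in the other 3 libraries (gap over range 0.875), and the mean log2 CPM of the milk protein list 8.51 against 14.5 to 15.04 (0.922). CSN2 (0.911) and LALBA (0.933) stood as far below the others. In the same library glucose uptake and lactose synthesis had a mean log2 CPM of 4.89 against 5.63 to 5.77 (0.842), amino acid transporters 4.50 against 5.36 to 5.38 (0.979), prolactin and STAT5 signalling 7.05 against 7.43 to 7.49 (0.860) and the integrated stress response 3.48 against 5.56 to 5.93 (0.849). SLC2A1 (0.991), SLC7A5 (0.891), NUDT12 (0.918) and SLC41A1 (0.924) were lower there too. Glycolysis, at 6.41 against 5.66 to 5.75 (0.876), and the cell cycle, at 4.44 against 0.83 to 1.16 (0.908), were higher.

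In other libraries low-dose replicate 2 was high in branched-chain amino acid breakdown (4.95 against 4.78 to 4.80, gap over range 0.897) and low in inflammation and acute phase genes (2.71 against 3.78 to 3.89, 0.912) and in ARG2 (0.880). Low-dose replicate 3 was high in T and NK cell markers (4.396 against 3.70 to 3.76, 0.920). High-dose replicate 4 was high in luminal epithelial markers (7.12 against 6.67 to 6.74, 0.831), high-dose replicate 2 in MTIF3 (0.860), and high-dose replicate 1 was low in DOCK10 (0.946).

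Middle-dose replicate 3 lay apart from the rest of its dose and nearest to low-dose replicate 2 (rho 0.985 over all genes listed for the libraries). On that scale its next nearest was high-dose replicate 1 (0.974), ahead of low-dose replicates 1 (0.969), 4 (0.965) and 3 (0.947). A smaller epithelial share of the biopsy would lower all epithelial transcripts. In middle-dose replicate 3 luminal epithelial markers lay at a median log2 of 0.26 relative to the other 3 middle-dose libraries (SD over genes 0.85). Its milk protein genes lay at -6.20, which argues against a smaller luminal epithelial share as the cause. The luminal list did not follow the milk protein share within doses (Pearson's r = -0.20, exact permutation p = 0.602), so it cannot decide on the share of secretory cells. An exchange with a low-dose library would place a low-dose library nearer to the other middle-dose libraries than to its own dose, and 0 of 4 were. Low-dose replicate 3 came close, with a mean rho of 0.950 with them and 0.956 with its own dose. Grouping it with them, and middle-dose replicate 3 with the low dose, gave 1683 genes past the threshold by edgeR, against 0 in the real groups. Such an exchange was therefore not excluded. Exchange with a high-dose library also stays open, since 1 of 4, high-dose replicate 2, was nearer to the other middle-dose libraries (mean rho over all genes listed for the libraries 0.969 against 0.963 with its own dose). Over the genes tested, on another scale, middle-dose replicate 3 itself had a mean rho of 0.954 with the low dose and 0.946 with the high, an order that rests on low-dose replicate 2. A single wrong label, which was not tested, or a gland that secreted less could also give these values.

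The gene lists that differed between the middle and low doses were weighed next. Heavy use of the counts by a few genes would end the calls once those genes are gone. With the milk protein genes left out and no composition scaling 21 of 22 called lists kept call and direction, all but the ChREBP targets (0.0575), which argues against it as the whole cause. That setting moved the median log2 of all genes to -0.20, from -0.86 by library size alone with these genes in, where 14 of 23 lists kept their call. With table layout as a term 23 of 23 did. Each of these doses had 1 library in the layout of 4 libraries, so the term could hardly move their difference. That balance, rather than the refit, argues against a batch marked by the layout. A lower epithelial share in the low-dose biopsies would raise markers of all other cell types alike. Endothelial minus macrophage scores differed by 1.39 (SE 0.452, exact permutation p = 0.0571), endothelial markers being higher at the middle dose and macrophage markers lower. These 2 lists were chosen after their directions were known, so their difference cannot decide the question. Such a share would also lower luminal epithelial markers at the low dose. Their mean log2 CPM was 6.53 to 6.94 there and 6.15 to 6.87 at the middle dose. The 2 ranges overlap. Without middle-dose replicate 3 the median log2 of these markers for middle against low was -0.47, opposite to that prediction, but camera did not call the list (adjusted p = 0.0881). A lower epithelial share was thus not excluded as part of the cause. The glucose dose stays open beside that share and chance. Of the 35 splits of the 8 libraries 2 gave at least as many lists (23 in the real split, 24 in the highest other), so chance was not excluded. That other split grouped low-dose replicates 1, 3 and 4 with middle-dose replicate 3.

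For the other counts of lists, 6 of 35 splits gave as many for high against low (16 real, 19 in the highest other) and 21 of 35 for high against middle (10 real, 18 highest), so chance was not excluded. No gene passed edgeR's threshold in the real groups, so all splits gave at least as many genes, which decides nothing. These were 35 of 35 for high against low (0 real, 7 highest), middle against low (0 real, 1683 highest) and high against middle (0 real, 1270 highest). They were 100 of the 100 splits of all 12 libraries for the middle-dose test (0 real, 1185 highest) and for any difference (0 real, 972 highest). Counts at unadjusted p under 0.05 can decide. Of 35 splits, 5 gave as many for high against low (1560 real, 2828 highest), 2 for middle against low (3234 real, 4225 highest) and 3 for high against middle (2029 real, 3770 highest), and 6 of 100 did for the middle-dose test (2989 real, 4003 highest), so chance was not excluded for these. For any difference 3 of 100 did (2913 real, 3769 highest), a share under 5% in 1 of 5 such counts, chosen afterwards and not adjusted over the 5, so it does not firmly exclude chance. The correlation of the changes from the low dose was as high in 26 of 100 splits (0.640 real, 0.812 highest), so chance was not excluded. Splits that call so many genes point to a structure of the samples that does not follow the doses. The split with 1683 set low-dose replicates 1, 2 and 4 and middle-dose replicate 3 against low-dose replicate 3 and the other middle-dose libraries. The split with 1270 set high-dose replicates 1, 3 and 4 and middle-dose replicate 3 against high-dose replicate 2 and the other middle-dose libraries.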

How the results depend on the processing

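Table layout as a term, the 8 libraries of the larger layout, fry, the list tests by library size alone or without milk protein genes, and both together were chosen after the result was seen; the other settings were chosen before. The 5 counts of genes stayed at 0 by edgeR with DESeq2's size factors, library size alone, no filter, milk protein genes left out and table layout as a term. DESeq2 called 51, 1396, 257, 1027 and 1083 genes (high against low, middle against low, high against middle, middle dose, any difference), and limma voom with quality weights 0, 4701, 859, 4169 and 3839. The larger layout alone gave 8 for high against low and 1 for any difference. Leaving out each library gave 0 to 19, 0 to 2390, 0 to 505, 0 to 2170 and 0 to 1289 genes, with the highest without high-dose replicate 1 for the first and without middle-dose replicate 3 for the others. Camera with an estimated correlation and fry called 0 lists in each comparison, against 16, 23 and 10. Library size alone gave 15 lists for middle against low and 16 for high against middle, and leaving out each library gave 9 to 18 for high against middle. The correlation of the changes from the low dose was 0.497 to 0.703 over libraries left out and 0.374 with the low-dose libraries split. Signs turned for HK2 in high against low over libraries left out (-0.024 to 1.28), for TXNIP with library size alone (-0.77 in middle against low, 0.18 in high against middle), for SLC2A1 in high against middle with limma voom (-0.079) and over libraries left out (-0.18 to 0.36), and for B4GALT1 in high against middle with library size alone (0.33) and in the larger layout (0.037). The cause was not tested.

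The replicate numbers did not pair the libraries: of 12 pairs with the same number 4 had deviations correlated above 0.1 (-0.53 to 0.38 over pairs), and 1 library correlated best with its own number. A replicate block gave 0 genes by edgeR in the 5 tests and no list count moved by over 1.5 times. Of 54 values of single genes 54 kept direction and call under the block, and of 49 called lists 45 did. Simulated 2-fold differences were recovered in 25% of cases for middle against low, and in 55% with 0.5 of the estimated spread within doses. Depth was not varied.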

Other observations

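The tests of pathways, of genes with separate levels, of casein ratios and of a list without LALBA were chosen after the result was seen; the relation of gene lists to the milk protein share was chosen before. Among the pathway terms that the tables give, 274 with 15 to 300 genes were tested with camera. Of the 274, 39 passed for high against low (20 higher, 19 lower) and 45 for middle against low (17 higher, 28 lower). For high against middle 4 passed, all higher. In each comparison 0 did with an estimated correlation (smallest adjusted p = 0.858, 0.610 and 0.956 with an estimated correlation). At the high dose protein processing in the endoplasmic reticulum (154 genes, median log2 0.32, adjusted p = 8.68e-13), ribosome biogenesis (70 genes, 0.43, 1.24e-10), protein export (22 genes, 0.48, 3.15e-06) and N-glycan synthesis (43 genes, 0.28, 1.51e-05) were higher than at the low dose, and primary immunodeficiency genes (27 genes, -0.63, 1.17e-08) lower, all lost with an estimated correlation (adjusted p at least 0.858). At the high against the middle dose the proteasome (41 genes, 0.31, 2.83e-05) and ribosome biogenesis (0.35, 2.83e-05) were higher, and these too were lost with an estimated correlation (at least 0.956).

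Interferon-induced genes stood out in low-dose replicate 4 alone. ISG15 was at 68.6 CPM there and at most 7.77 CPM in the other 11 libraries, and MX1 at 358 CPM against 16.5 to 58.8 CPM. Caseins were not made in one ratio: CSN1S1 came to 3.23, 3.72 and 4.39% of CSN2 in middle-dose replicates 4, 1 and 2 and to 4.61% in low-dose replicate 3, but to 0.208 to 1.32% in the other 8 libraries, 0.691% in high-dose replicate 2 although its CSN2 reached 310595 CPM. Genotype was not analysed here. Separate levels across libraries were sought among genes above 5 CPM in some library. The rule asked for a gap above 2 on the log2 scale and above 5 times the SD within either level, with at least 2 libraries on each side. It found 5 genes, and 0 of them split along a dose. RBM12 was at 2.80 to 4.24 CPM in low-dose replicates 2 and 4 and middle-dose replicate 2 and at 64.4 to 136 CPM in the other 9. LOC102180584 had 0 reads in high-dose replicates 2 and 4 and middle-dose replicates 1 and 4 and 24.1 to 98.4 CPM elsewhere. LOC102184389 was at 0.950 and 1.26 CPM in low-dose replicates 1 and 2 and at 58.1 to 270.1 CPM elsewhere. LOC102173177 was at 17.0 to 54.8 CPM in low-dose replicates 1, 2 and 3 and middle-dose replicate 2 and at most 1.02 CPM elsewhere. CCNB1, a mitotic cyclin, was at 0.972 to 1.91 CPM in high-dose replicates 2 and 4 and middle-dose replicates 1, 2 and 4 and at 9.87 to 19.2 CPM in the other 7.

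A hypothesis is that the secretory state of the sampled gland differed between libraries of one dose. If so, lists of milk synthesis would follow the milk protein share within doses. Over the 12 libraries, with dose means removed, 8 of 36 lists were correlated with the log2 milk protein share at an exact permutation p under 0.05 after adjustment (13824 orders within doses), 6 positively and 2 negatively. Triglyceride synthesis and fat globule secretion had Pearson's r = 0.933 (adjusted exact p = 0.0234, unadjusted 0.00116) and Spearman's rho = 0.909 (adjusted 0.0243), and r = 0.898 without the 2 libraries farthest from the median share, middle-dose replicate 3 and low-dose replicate 2. Glucose uptake and lactose synthesis had r = 0.899 (adjusted exact p = 0.0292) and rho = 0.916, with r = 0.851 without the 2. LALBA belongs to this list and to the milk protein genes, and without it r was 0.681 (unadjusted exact p = 0.0399) and rho 0.629 (0.0382), with r = 0.524 without the 2. Amino acid transporters had r = 0.864 (adjusted exact p = 0.0417) and rho = 0.832, with r = 0.730 without the 2. Cholesterol synthesis had r = 0.83 (adjusted exact p = 0.0234) and rho = 0.776, with r = 0.825 without the 2. Glycolysis (r = -0.925, adjusted exact p = 0.0292, rho = -0.790, r = -0.883 without the 2) and the cell cycle (r = -0.843, 0.0417, rho = -0.685, r = -0.718 without the 2) went against it. Fatty acid synthesis and uptake (r = 0.767, adjusted exact p = 0.0269) and prolactin and STAT5 signalling (r = 0.744, 0.0417) missed the threshold by rho (0.0578 each). All 8 kept their sign without the 2 farthest libraries, but the dose means removed there still included those 2. With dose means taken again without middle-dose replicate 3, all 8 kept their sign with r smaller in size. It was 0.862 for triglyceride synthesis, 0.792 for glucose uptake and lactose synthesis, 0.707 for amino acid transporters and 0.678 for cholesterol synthesis. For fatty acid synthesis r was 0.656, for prolactin and STAT5 signalling 0.628, for glycolysis -0.827 and for the cell cycle -0.664. Within the 8 libraries of the larger table layout r ranged from 0.859 to 0.986 for the 6 and was -0.924 for glycolysis and -0.840 for the cell cycle. Both middle-dose replicate 3 and low-dose replicate 2 are among these 8. The layout of 4 libraries was too small for a value. A differing share of secretory cells in the biopsies could give the same correlations, so they do not separate it from such a state. A chance imbalance of either between doses may add to the differences between doses in these 8 lists. The design does not separate that imbalance from an effect of glucose.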
